A study of Homo sapiens with 9 samples.

How the data were processed

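RNA sequencing was done on 9 libraries of ACHN cells, an established human renal cell carcinoma line. The groups, taken from the labels, were sgControl (cells given a control guide RNA), KO#1 and KO#2 (cells in which ELOVL5 was targeted with CRISPR/Cas9 and 1 of 2 independent guides), with 3 libraries each. The labels give no replicate numbers, so those used here are places in sample order within each group, which name libraries and state no pairing. The labels do not say that the replicates of a group are separate cultures, so the p-values measure only the spread between these samples, which may be technical. Nor do they say whether the knockout cells were grown from single clones or kept as pools.

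Per the labels' protocols, total RNA was purified with RNeasy Mini columns, strand-specific libraries were made with the NEBNext Ultra Directional kit, and paired ends were read on a NextSeq500. The deposited table holds 57773 features by gene name. Its values are a signal that the authors derived from total read counts per gene by quantile normalization, as the table's own name states. The aligner, the counter and the handling of strand are not given in the sources used here. The submitters' processing notes list the genome build mm10, a mouse build, although the gene names in the table are human; no coordinates are therefore given here, and genes of near-identical sequence, or overlapping on the same or opposite strands, are uncertain. The values fit the statement on normalization: all 9 libraries hold one and the same set of sorted values (0 ranks differ), from 0 to 89242.1, with a total of 8625043.6 in each. All values are multiples of the smallest value above 0, 0.1111. Raw library totals cannot be had from such values, so the table was tested on a log scale and no model for counts was fitted. In all, 34550 features were at 0 in every library. Of 27 names that a spreadsheet had turned into dates, 21 were tested, and 84 of 2234 features with a numbered suffix were tested; none of these is named. No sample column was left unused (0), and 0 pairs of libraries had identical values.

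Quantile normalization gives features with equal reads in a library different values by their order in the table. Runs of features in table order therefore mark features with equal low read numbers, and the number of features at or above 1 to 10 reads could be read back for each library. On simulated data the largest error of that number was 0.0%. This reading was devised after the values had been seen. Between 16085 and 17421 features had at least 1 read in 8 of the libraries, and 14658 in KO#2 replicate 1. A feature with 10 reads had a value of 6.667 to 12.556 in those 8 libraries and of 55.667 in KO#2 replicate 1, so that low values rest on fewer reads in that library than in the others.

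Values were transformed to log2(value + 1), and the 12985 features with a mean of at least 10 over the 9 libraries were tested. All fold changes are on this scale, which understates the change of genes with low values. limma 3.58.1 (R 4.3.3) fitted 1 linear model with 3 groups to all libraries, with empirical Bayes moderation and a trend of variance on mean. Tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were KO#1 and KO#2 each with sgControl, the mean of both with sgControl, KO#2 with KO#1, and the genes called with the same sign by both guides. SE is the moderated standard error of the log2 fold change, SD is between libraries, and n is 3 libraries per group unless said otherwise. A gene at 0 in all libraries of a group is said to be listed at 0, with no fold change.

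The tests, alternatives, rule for named genes and 25 gene lists were written before the data were examined. The lists covered very-long-chain fatty acid elongation and desaturation, fatty acid synthesis, cholesterol synthesis, lipid droplets, fatty acid oxidation, phospholipid remodelling, the unfolded protein response, ATF4 targets, mitosis, DNA replication, p53 targets, apoptosis regulators, FOXO targets, STAT3 targets, mesenchymal and matrix genes, renal and epithelial identity, hypoxia-inducible factor targets, the interferon response, NF-kB targets, NRF2 targets, markers of other cell types, mitochondrially encoded messenger RNAs, cytosolic ribosomal proteins, replication-dependent histones, and immediate early and heat shock genes. Lists with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, Benjamini-Hochberg adjusted over the 24 lists. A second run estimated the correlation for each list, and fry tested whether the members of a list moved one way on balance without comparing them with other genes. The text names ELOVL5; of the genes called alike with both guides, with a gene symbol and a mean value above the median of tested genes, the 10 higher and 10 lower with the largest smaller absolute fold change; by the same conditions the 3 higher and 3 lower of each guide and up to 5 each way between the guides; for each list up to 4 members with the smallest p for the mean of both guides; and the ELOVL family, FADS1, FADS2 and SCD. Other genes are marked as chosen after their values were seen.

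The alternatives were a pseudocount of 0.1 or 8, no filter or a mean of at least 100, rescaling by median ratios, a second quantile normalization, no variance trend, robust moderation, library weights (arrayWeights, gene-by-gene method, taken after the default had not converged), only the 2 groups compared, a log2 fold change of at least 1, camera on ranks, and leaving out each library in turn. Further choices were made after seeing the data. The first removed, in each library, the trend of gene deviations on GC content (a natural spline). The second kept the same genes without the correction. The third removed the running median of 51 neighbouring genes. The fourth, called the replicate block, added the place in sample order to the model as a factor, and the fifth combined it with the GC correction. GC content was that of the longest protein-coding transcript in GENCODE v29. By name 11495 tested genes matched, by older symbol 478 more, in all 92.21%. The order of genes along chromosomes came from the same match.

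Comparisons with the same sgControl libraries share their chance values, so the overlap of both guides was set beside 100 simulations of unchanged groups against shared controls. The pipeline was tested on simulated data with 200 changed genes at 3 libraries per group. With 12828 genes tested, limma recovered 99% of 4-fold changes for KO#1 and 97% for KO#2, and 42% and 40% of 2-fold changes. With 1 noisy KO#2 library (12785 genes), it recovered 11.11% and 31.31% of 4-fold and 0% and 1% of 2-fold changes. With a GC trend in 1 library (11663 genes), 70.5% and 59% of 4-fold changes were recovered before the correction and 99.5% and 98% after it; calls among unchanged genes numbered 0 and 1 before it and 8 and 15 after. Windows of neighbouring genes were tested with 1 chromosome shifted by 0.5 on the log2 scale: 6 of 6 windows on it were found and 0 of 209 others (11579 genes). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the table and drew the plots.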

Results

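Messenger RNA levels were measured in ACHN renal carcinoma cells in which ELOVL5, an elongase that lengthens polyunsaturated fatty acids, was targeted with either of 2 CRISPR guides. The series is about the part of ELOVL5 in the growth and invasion of renal cell carcinoma. There were 3 libraries each of sgControl, KO#1 and KO#2 cells. All 9 libraries had the same total signal of 8625043.6 after the authors' normalization, so their raw depth is unknown. KO#2 replicate 1 stood apart. Its correlation across genes with the other KO#2 libraries was 0.672 and 0.737 on the log2 scale, where sgControl and KO#1 libraries correlated with their own group at 0.958 to 0.978. In that library 10257 features had at least 10 reads, against 12421 to 13254 in the others. Mitochondrial transcripts took 7.002% of its signal and 5.304% to 6.287% of that of the others. A weight estimated from the data by limma was 0.0547 for this library and 0.508 to 2.52 for the rest. Genes were called with it included, and the values without it, an alternative set before the data were examined, are given beside the counts and for named genes they bring to pass.

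The first comparison asks whether the targeted transcript itself was lower. ELOVL5 had signals of 1999, 2713 and 2063 in the sgControl libraries (mean 2259 ± 395, SD, n = 3), of 805, 1345 and 1016 in KO#1 (1055 ± 272) and of 434, 1805 and 910 in KO#2 (1050 ± 696). All 6 KO libraries lay below the lowest sgControl library. The log2 fold change was −1.11 (SE 0.467) with KO#1 and −1.32 (SE 0.467) with KO#2, and neither passed the test (limma, Benjamini-Hochberg adjusted p = 0.383 and 0.24). Editing by Cas9 can disrupt a protein and leave its transcript in place. With all libraries, the 7 other tested elongase and desaturase genes named here did not pass the test with either guide. ELOVL6, which elongates saturated chains, had log2 fold changes of 1.16 and 1.28, ELOVL2 of −0.98 and −1.01, ELOVL7 of −0.67 and −0.26, and ELOVL1 of −0.10 and −0.08. FADS1 had −0.50 and −0.18, FADS2 −0.26 and 0.40, and SCD −0.39 and 0.27 (adjusted p from 0.388 to 1.00 for these 7 genes). The ELOVL5 call depended on single libraries. Without KO#2 replicate 1 ELOVL6 rose with KO#2 (1.96, adjusted p = 0.0216), and the adjusted p of ELOVL5 was 0.0314 with KO#1 and 0.162 with KO#2 (−0.80), and without KO#2 replicate 2 it was 0.0383 with KO#2 (−1.83). Over all alternatives it ranged from 0.00266 to 0.942 with KO#1 and from 0.0103 to 0.527 with KO#2.

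**Figure D1:**
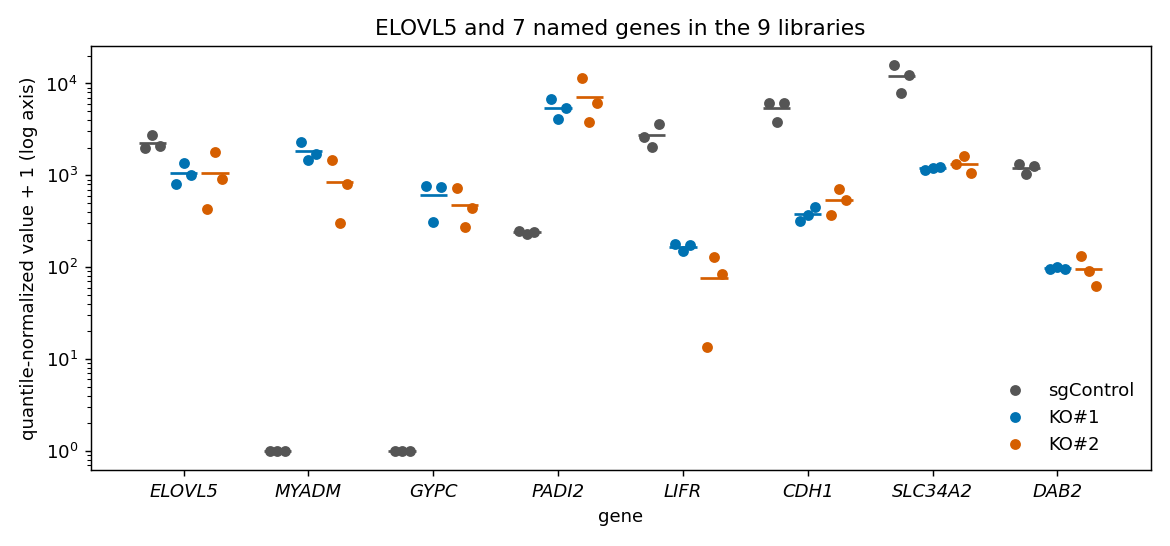
Signal plus 1, on a log axis, of 8 genes in the 9 libraries; points are libraries and lines are group means. ELOVL5 lay at 434 to 1805 in the KO libraries and at 1999 to 2713 in sgControl, while MYADM and GYPC were listed at 0 in all 3 sgControl libraries.

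Genes that changed alike with both guides answer what the cells shared after ELOVL5 targeting. Some transcripts that were near absent in sgControl cells, such as MYADM and GYPC, were abundant in KO cells. Others, such as PADI2 and CDH13, were present in sgControl cells and rose. MYADM, a membrane protein of the myelin and lymphocyte family, was listed at 0 in all sgControl libraries and had signals of 2332, 1475 and 1701 in KO#1 and of 1461, 301 and 799 in KO#2 (limma, Benjamini-Hochberg adjusted p = 1.03e-05 and 1.5e-05). GYPC, the red cell membrane protein glycophorin C, was likewise listed at 0 in sgControl and had 755, 307 and 747 in KO#1 and 722, 273 and 444 in KO#2 (adjusted p = 1.04e-05 and 1.5e-05). The zinc finger gene ZNF469 rose from 0.407 ± 0.257 to 1319 ± 1026 and 967 ± 891 (SD, n = 3; log2 fold change 9.62 and 8.60, SE 0.961, adjusted p = 0.000642 and 0.00145). IL31RA, a receptor subunit for interleukin-31, rose from 4.96 ± 0.128 to 405 ± 109 and 401 ± 221 (6.05 and 5.90, SE 0.472, adjusted p = 0.000157 and 0.000203). DYSF, which encodes the membrane repair protein dysferlin, rose by 7.01 and 5.64 (SE 0.751, adjusted p = 0.00101 and 0.00378), and KIAA1244 by 6.26 and 5.36 (SE 0.634, adjusted p = 0.00069 and 0.0018). ARMCX2 rose by 5.21 and 5.05, and FUCA2, a secreted fucosidase, by 5.02 and 4.85 (adjusted p from 8.94e-05 to 0.000179). PADI2, which converts arginine to citrulline in proteins, was the most abundant of these genes and rose from 238 ± 9.99 to 5403 ± 1328 and 7129 ± 3903 (4.47 and 4.75, SE 0.393, adjusted p = 0.000335 and 0.000233). CDH13, or T-cadherin, rose from 29.3 ± 12.2 to 473 ± 138 and 350 ± 136 (SE 0.449, adjusted p = 0.00131 and 0.00288).

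The calls of these 10 genes held with each library left out in turn, the highest adjusted p being 0.0151 in KO#1 (CDH13) and 0.0252 in KO#2 (DYSF). HYDIN, a gene of motile cilia, and TRPS1, a GATA-family repressor, were chosen after their values were seen. HYDIN was listed at 0 in sgControl and had 293, 187 and 210 in KO#1 and 280, 161 and 232 in KO#2. TRPS1 was listed at 0 in sgControl and had 101, 121 and 169 in KO#1 and 84.2, 127 and 207 in KO#2.

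Among the genes lower with both guides, CDH1, which encodes the adhesion protein E-cadherin, fell from 5357 ± 1323 to 381 ± 68.3 and 543 ± 173 (SD, n = 3; log2 fold change −3.79 and −3.32, SE 0.342, limma, Benjamini-Hochberg adjusted p = 0.000335 and 0.000764). SLC34A2, a sodium-dependent phosphate transporter, fell from 12050 ± 3989 to 1196 ± 52.3 and 1341 ± 293 (−3.27 and −3.13, SE 0.322, adjusted p = 0.000578 and 0.000764). The endocytic adaptor DAB2 fell from 1209 ± 152 to 96.0 ± 2.48 and 93.7 ± 34.6 (−3.63 and −3.73, SE 0.344, adjusted p = 0.000413 and 0.00053). LIFR, the receptor for leukaemia inhibitory factor, fell from 2759 ± 824 to 166 ± 13.8 and 75.3 ± 58.8 (SE 0.691, adjusted p = 0.013 and 0.00232). PRUNE2 fell from 1020 ± 123 to 39.4 ± 8.94 and 36.2 ± 28.6 (−4.67 and −5.40, SE 0.779, adjusted p = 0.0107 and 0.00554). The small GTPase gene RHOB fell by 2.45 and 2.39, and SEMA5A, a semaphorin, by 3.16 and 2.71 (adjusted p from 0.00153 to 0.00876). DPP4, a peptidase of the kidney brush border, had changes of −2.77 and −3.53, ALDH1A1, a retinal dehydrogenase, −2.68 and −2.75, and EDN2, or endothelin-2, −3.74 and −3.19 (adjusted p from 0.00546 to 0.0335).

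Calls of 6 of these lower genes were lost when 1 of several libraries was left out. With KO#1, that of ALDH1A1 was lost without any sgControl or KO#1 library (limma adjusted p 0.0736 to 0.106), as was that of DPP4 (0.05001 to 0.0988). LIFR and EDN2 were lost without sgControl replicate 1 or 3 or any KO#1 library (0.0640 to 0.0830 and 0.05001 to 0.0859), and PRUNE2 without any sgControl library or KO#1 replicate 1 or 2 (0.0520 to 0.0664). With KO#2, ALDH1A1 was lost without any sgControl library (0.0770 to 0.108), EDN2 without any sgControl or KO#1 library (0.0592 to 0.166), and SEMA5A without sgControl replicate 1 (0.0650) or 3 (0.0509). Each of the calls lost in this way held without KO#2 replicate 1 (limma adjusted p 4.87e-06 to 0.00341 in KO#1 and 0.00169 to 0.0117 in KO#2). Once the median of neighbouring genes was removed, a setting chosen after seeing the data, DAB2 had −2.91 in KO#1 (adjusted p = 0.0359) and −2.51 in KO#2 (SE 0.637, 0.075), and ALDH1A1 and EDN2 had 0.0885 and 0.118 in KO#2 when only the 2 groups compared were fitted.

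In all, 303 of 12985 genes were called with KO#1 (177 higher, 126 lower), 265 with KO#2 (152 higher, 113 lower), and 179 alike with both (120 higher, 59 lower). Among called genes with a mean above the median of tested genes, MYADM, GYPC and ZNF469 had the largest increases with each guide. PRUNE2, LIFR and CDH1 had the largest decreases of these with KO#1, and LIFR, PRUNE2 and SCN9A with KO#2; some less abundant genes, CCL2 among them, fell by more. SCN9A, a voltage-gated sodium channel, had −3.22 with KO#1 (limma, Benjamini-Hochberg adjusted p = 0.106; 9.52e-05 without KO#2 replicate 1) and fell by 4.17 with KO#2 (SE 0.861, adjusted p = 0.0343), a call lost without any sgControl or KO#1 library (0.0654 to 0.167). For the mean of both guides 403 genes were called (214 higher, 189 lower). At an unadjusted p under 0.05 there were 1467 genes for KO#1 and 1757 for KO#2, where 649.25 were expected by chance. The counts moved with the libraries used. Without KO#2 replicate 1 they were 1592, 1042 and 798 alike (397 higher, 401 lower), and all 179 genes called alike were among the 798 with the same sign. Without sgControl replicate 1, 2 or 3 they were 107, 168 and 112 for KO#1, 95, 144 and 104 for KO#2, and 66, 101 and 70 alike. Without KO#1 replicate 1, 2 or 3 they were 96, 128 and 107 for KO#1, 175, 165 and 165 for KO#2, and 72, 90 and 78 alike. After a GC content correction chosen after seeing the data they were 1053, 972 and 629 alike (296 higher, 333 lower), and 171 of the 172 genes called alike that had a known GC content remained.

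Both comparisons share the sgControl libraries. The log2 fold changes of the guides correlated across genes at r = 0.731, where unchanged groups simulated against shared controls gave 0.279; genes are not independent replicates. The covariance was 0.622 against a simulated 0.0585. The same sign was seen in 66.9% of genes against 59.0% simulated, and 179 genes were called alike against 0 simulated. The simulated groups held no changed gene, so calls were rare by design. That 0 therefore cannot size the overlap of called genes due to the shared controls. Independent lists of these sizes, which leave the shared controls out, would share 2.07 higher and 1.1 lower genes, against 120 and 59 observed. The 3 controls could not be split into sets of at least 2, and part of the excess may come from the shared controls.

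**Figure D2:**
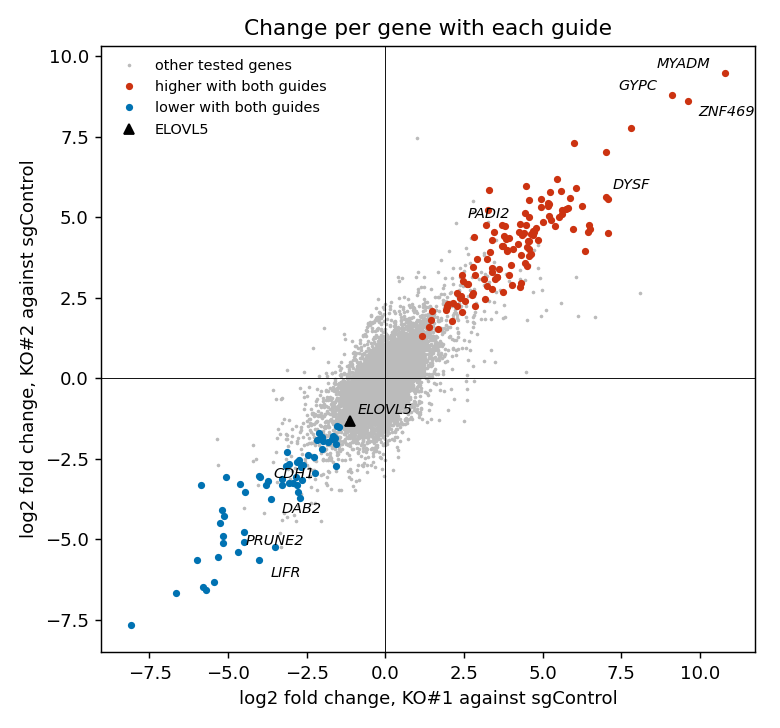
Log2 fold change against sgControl with KO#1 (x axis) and KO#2 (y axis), 1 point per tested gene; coloured points are the 179 genes called alike and the triangle is ELOVL5 (−1.11 and −1.32). The position of genes listed at 0 in sgControl, such as MYADM and GYPC, depends on the 1 added before the logarithm.

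Lipid genes were examined because ELOVL5 acts in fatty acid metabolism. In the list of very-long-chain fatty acid elongation and desaturation, 0 of 15 tested members passed over all genes with either guide (limma), though the list as a whole was lower with KO#1 (median log2 fold change −0.39, camera, Benjamini-Hochberg adjusted p = 0.0444; adjusted p = 0.684 with an estimated correlation). The list holds the targeted gene ELOVL5 itself (−1.11 with KO#1) and was not tested without it. SCD5, a desaturase, and ACSL1, which activates long-chain fatty acids, had changes of −1.30 and −1.86 with KO#1 and made up the 2 genes that passed when adjusted over the list alone. Over all genes, 1 higher and 4 lower members passed with KO#1 and 2 higher and 1 lower with KO#2 without KO#2 replicate 1, including SCD5 (limma adjusted p = 0.00866) and ACSL1 (0.000243) with KO#1. ACSL1 in KO#1 also passed without KO#2 replicate 2 (0.0438). With KO#2 the list's median was −0.26 and 0 members passed when adjusted over the list alone (adjusted p = 0.388; adjusted p = 0.911 with an estimated correlation). The KO#1 call was lost without sgControl replicate 2 (0.0792), KO#1 replicate 1 (0.156), KO#1 replicate 3 (0.101) or KO#2 replicate 3 (0.0527).

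The 19 tested genes of fatty acid synthesis and SREBP1 targets held 0 called members with either guide, and 0 adjusted over the list alone. LPIN1 had −1.31 and −0.53, PNPLA3 0.31 and 1.22, and FASN, the fatty acid synthase, 0.33 and 0.96 (limma adjusted p from 0.132 to 0.957). Over all genes, 2 lower members, LPIN1 (0.018) among them, passed with KO#1 and 1 higher with KO#2 when KO#2 replicate 1 was left out. The list's medians were −0.28 and −0.05 (camera, Benjamini-Hochberg adjusted p = 0.143 and 0.649; adjusted p = 0.684 and 0.911 with an estimated correlation); with KO#2 the mean was 0.12 and the test pointed up. The list passed with KO#1 without sgControl replicate 3 (0.0243) or KO#1 replicate 2 (0.0055). Of 25 cholesterol synthesis and SREBP2 target genes 0 passed with either guide. When adjusted over the list alone, 0 passed with KO#1 and 1, as higher, with KO#2. HMGCS1, which makes a precursor of mevalonate, had changes of −1.47 and −1.43, and FDFT1, the squalene synthase, 0.38 and 0.86. The cholesterol medians were −0.38 and 0.28 (adjusted p = 0.0999 and 0.465; adjusted p = 0.795 and 0.911 with an estimated correlation), and the list passed with KO#1 without sgControl replicate 3 (0.00184) or KO#1 replicate 2 (0.000152). With KO#2 replicate 1 left out, 1 cholesterol member was higher with each guide.

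Among 21 lipid droplet and triglyceride genes, FABP3, a fatty acid binding protein of muscle, rose with KO#2 (log2 fold change 5.50, SE 0.738, limma, Benjamini-Hochberg adjusted p = 0.00382) from 0.148 ± 0.257 to 63.6 ± 53.8, and had 2.77 with KO#1 (adjusted p = 0.104). It was the 1 member called; 0 were called with KO#1. With p adjusted over the list alone, 2 higher (FABP3, FITM2) and 1 lower (LPIN1) passed with KO#1, and FABP3 and FITM2 with KO#2. FITM2 had 1.34 and 1.63, and DGAT2, which makes triglycerides, 1.31 and 1.55. Leaving out KO#2 replicate 1 gave 3 higher and 3 lower members with KO#1 and 2 higher and 2 lower with KO#2. These included FABP3 (0.011) and DGAT2 (0.0439) with KO#1 and FITM2 with both (0.00589 and 0.0204). The medians were 0.17 and 0.18 (camera adjusted p = 0.611 and 0.241; adjusted p = 0.795 and 0.626 with an estimated correlation). Of 26 fatty acid oxidation and PPAR target genes 0 passed with either guide, over all genes or adjusted over the list alone. ACAA2 had −2.79 and −3.97, ETFA 1.02 and 0.73, DECR1 1.2 and 0.43, and ANGPTL4 1.61 and 1.14. When KO#2 replicate 1 was left out, 3 rose and 1 fell with KO#1, and 1 rose and 1 fell with KO#2: ETFA rose (limma adjusted p = 0.0084 and 0.017) and ACAA2 fell (0.00116 and 0.01003) with both, and DECR1 (0.0198) and ANGPTL4 (0.0106) rose with KO#1. ACAA2 in KO#2 also passed without KO#2 replicate 2 (0.0317). The oxidation medians were 0.06 and 0.10 (adjusted p = 0.639 and 0.955; adjusted p = 0.795 and 0.951 with an estimated correlation), and with KO#2 the mean of −0.10 and the test pointed down.

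Of 22 genes of phospholipid remodelling and eicosanoid synthesis, 1 rose and 1 fell with each guide. PLA2G4A, a phospholipase that releases arachidonic acid from membranes, rose from 7.59 ± 5.06 to 122 ± 12.9 and 57.7 ± 22.8 (log2 fold change 4.04 and 2.89, SE 0.561, limma, Benjamini-Hochberg adjusted p = 0.00438 and 0.0268). LPCAT1, which adds acyl chains to lysophosphatidylcholine, fell from 2796 ± 362 to 678 ± 287 and 876 ± 179 (−2.11 and −1.68, SE 0.339, adjusted p = 0.00915 and 0.0316). CYP2J2 had 1.4 and 1.80, and AKR1C3 −1.16 and −2.02. Without KO#2 replicate 1, 2 rose and 2 fell with KO#1 and 1 rose and 2 fell with KO#2, with CYP2J2 passing in KO#1 (0.0302) and AKR1C3 in KO#2 (0.0202). Adjusted over the list alone, 1 higher and 1 lower passed with KO#1, and 3 higher and 2 lower with KO#2. The medians were −0.02 and −0.12 (camera adjusted p = 0.602 and 0.908; adjusted p = 0.795 and 0.947 with an estimated correlation). PLA2G4A in KO#2 was lost without sgControl replicate 1 or 2, any KO#1 library, or KO#2 replicate 2 or 3 (0.0515 to 0.113). LPCAT1 was lost in KO#1 without sgControl replicate 1, KO#1 replicate 1 or KO#1 replicate 3 (0.0630 to 0.0665), and in KO#2 without any sgControl library, KO#1 replicate 1, KO#1 replicate 3 or KO#2 replicate 3 (0.0588 to 0.164); with the median of neighbouring genes removed it had −0.62 in KO#2 (SE 0.28, 0.352).

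**Figure D3:**
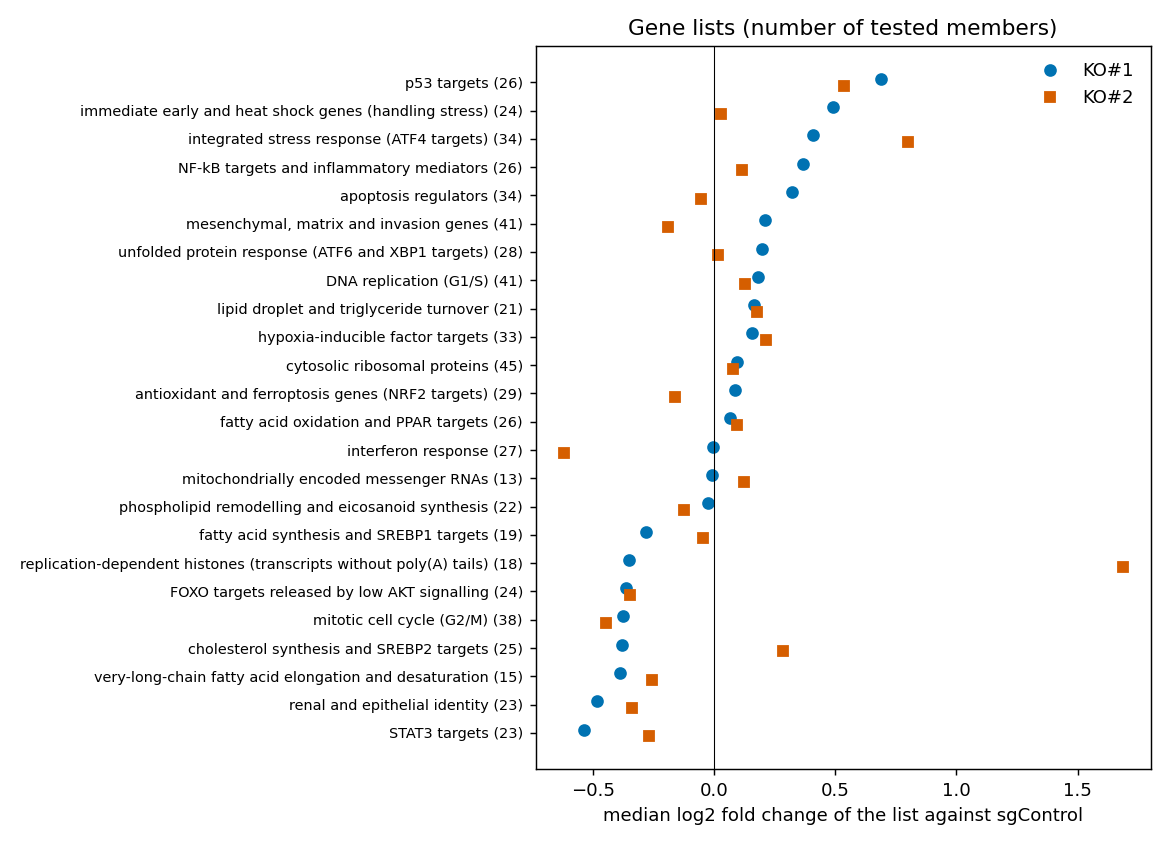
Median log2 fold change of each gene list with KO#1 and KO#2, with the number of tested members in brackets. The p53 targets lay at 0.69 and 0.54, the ATF4 targets at 0.41 and 0.80, and the replication-dependent histones at −0.35 and 1.69.

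Targets of ATF4, the transcription factor of the integrated stress response, were higher as a list with both guides. The median log2 fold change of 34 members was 0.41 with KO#1 and 0.80 with KO#2 (camera, Benjamini-Hochberg adjusted p = 0.0444 and 7.19e-06; adjusted p = 0.684 and 0.534 with an estimated correlation). With KO#1, 3 members rose and 1 fell, over all genes and adjusted over the list alone. SLC7A5 and SLC3A2, the subunits of a large neutral amino acid transporter, rose by 1.59 and 1.45 (SE 0.334 and 0.308, limma adjusted p = 0.0343 and 0.0372), and STC2, or stanniocalcin-2, by 1.59 (SE 0.35, adjusted p = 0.044). With KO#2 they had 1.23, 1.27 and 1.05 (adjusted p = 0.108, 0.0722 and 0.21). NUPR1, a stress-induced chromatin protein, went the other way, falling from 415 ± 189 to 23.6 ± 5.25 and 51.1 ± 26.9 (−4.01 and −3.02, SE 0.477, adjusted p = 0.00201 and 0.00891). With KO#2, 2 members rose and 1 fell, and 8 rose and 2 fell adjusted over the list alone. The members that rose, TRIB3 (2.23, SE 0.472, adjusted p = 0.0391) and SESN2 (1.81, SE 0.397, adjusted p = 0.0463), fell outside the naming rule and were chosen after their values were seen. With KO#2 replicate 1 left out, 4 rose and 2 fell with KO#1, and 8 rose and 1 fell with KO#2, SLC3A2 (0.0274), SLC7A5 (0.0357) and STC2 (0.0293) among them.

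The KO#1 call of the ATF4 list was lost without sgControl replicate 2 (adjusted p = 0.239), KO#1 replicate 3 (0.376), KO#2 replicate 1 (0.0728) or KO#2 replicate 3 (0.0507), and after GC correction (0.0789), while the KO#2 call held without any 1 library. SLC7A5, SLC3A2 and STC2 were lost in KO#1 without any sgControl or KO#1 library (limma adjusted p 0.0971 to 0.192, 0.103 to 0.216 and 0.0974 to 0.261), and STC2 also without KO#2 replicate 3 (0.0531). SLC7A5 had 1.04 in KO#1 (SE 0.458, 0.361) with the median of neighbouring genes removed. NUPR1 in KO#2 was lost without sgControl replicate 1 (0.0516) or 3 (0.0617). SESN2 in KO#2 was lost without any sgControl or KO#1 library or KO#2 replicate 3 (0.0775 to 0.195), and TRIB3 without any sgControl library, KO#1 replicate 2 or KO#2 replicate 3 (0.0777 to 0.174).

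The 28 tested genes of the unfolded protein response, which acts through ATF6 and XBP1, held 0 called members with either guide, and 0 adjusted over the list alone. XBP1 had 0.37 and 0.89, SDF2L1 0.55 and 1.27, PDIA3 0.82 and 0.49, and SEC61A1 0.33 and 0.42. The medians were 0.20 and 0.01 (camera, Benjamini-Hochberg adjusted p = 0.256 and 0.477; adjusted p = 0.795 and 0.911 with an estimated correlation). Without KO#2 replicate 1 the list passed with KO#2 (median 0.51, adjusted p = 0.003), and 2 members were higher with KO#2, XBP1 (limma adjusted p = 0.0384) among them, and 0 with KO#1. In that library the list's median deviation was −0.84, against 0.173 and 0.731 in the other KO#2 libraries.

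Targets of p53 were higher as a list with both guides, while 0 of 26 members passed limma's test over all genes with all libraries. The median was 0.69 with KO#1 and 0.54 with KO#2 (camera, Benjamini-Hochberg adjusted p = 0.000372 and 0.0321; adjusted p = 0.373 and 0.534 with an estimated correlation). When adjusted over the list alone, 3 passed as higher with KO#1 (AEN, TNFRSF10B and SESN1) and 2 with KO#2 (AEN and TNFRSF10B). AEN, a nuclease of apoptosis, had 1.13 and 1.30, TNFRSF10B, a death receptor for TRAIL, 0.98 and 1.03, GADD45A 0.93 and 0.74, and SESN1 1.25 and 0.62. With the median of neighbouring genes removed, AEN had 0.48 and 0.56 and TNFRSF10B 0.45 and 0.60. GADD45A then had 0.95 and 1.31, and SESN1 1.13 and 0.77 (limma adjusted p from 0.0866 to 0.485 for all of these). With KO#2 replicate 1 left out, 5 rose with KO#1 and 3 with KO#2, including AEN (limma adjusted p = 0.00148 and 0.00893) and TNFRSF10B (0.00587 and 0.00553) with both, and GADD45A (0.0304) and SESN1 (0.0173) with KO#1. AEN in KO#2 also passed without KO#2 replicate 2 (0.0462). The KO#1 call held without any 1 library, and the KO#2 call was lost without KO#2 replicate 2 (0.173) or 3 (0.0911). Of 34 apoptosis regulators 1 fell with each guide. BCL2, which blocks apoptosis at the mitochondrion, fell from 1035 ± 192 to 231 ± 44.6 and 289 ± 136 (−2.16 and −1.92, SE 0.37, limma adjusted p = 0.0126 and 0.026). BIK, which promotes apoptosis, had 1.2 and 1.80, and TNFRSF10A 1.1 and 0.97. With the median of neighbouring genes removed BIK had 1.31 and 1.62, and TNFRSF10A 0.57 and 0.51. When KO#2 replicate 1 was left out, 3 apoptosis genes rose with KO#1 and 4 with KO#2 and 1 fell with each, BIK (0.0403 and 0.0276) and TNFRSF10A (0.00525 and 0.00895) rising with both. With p adjusted over the list alone, 1 lower passed with KO#1, and 2 higher and 1 lower with KO#2. The medians were 0.32 and −0.05 (adjusted p = 0.256 and 0.649; adjusted p = 0.684 and 0.911 with an estimated correlation), and with KO#2 the mean was 0.06 and the test pointed up. BCL2 was lost in KO#1 without sgControl replicate 1 or 3 or any KO#1 library (0.05001 to 0.0877), and in KO#2 without any sgControl or KO#1 library or KO#2 replicate 3 (0.05002 to 0.156).

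Cell cycle genes were highest in replicate 2 of each group. Of 38 mitotic genes and 41 DNA replication genes, 0 passed with either guide in limma's 3-group model, over all genes or adjusted over the list alone. MKI67, the Ki-67 proliferation marker, had signals of 3651, 15284 and 2558 in sgControl, 1447, 11438 and 1790 in KO#1 and 593, 3303 and 1107 in KO#2 (log2 fold change −0.76 and −2.01, limma, Benjamini-Hochberg adjusted p = 0.952 and 0.371). ASPM had −0.99 and −1.90, CENPF −0.71 and −1.95, and CENPA −1.49 and −1.1. The mitotic medians were −0.38 and −0.44 (camera adjusted p = 0.171 and 0.0814; adjusted p = 0.795 and 0.911 with an estimated correlation). The mitotic list passed with KO#1 without sgControl replicate 1 (0.0122), sgControl replicate 3 (0.0121) or KO#1 replicate 2 (9.54e-08), and with KO#2 without sgControl replicate 1 (0.00459), sgControl replicate 3 (0.00453), KO#1 replicate 1 (0.0470), KO#1 replicate 2 (0.0336) or KO#2 replicate 2 (0.00017). The replicate block, chosen after seeing the data, uses places in sample order, which the labels do not make a pairing. In it MKI67, ASPM and CENPF passed as lower with KO#2 (limma adjusted p = 0.0189, 0.0333 and 0.0420) and 0 mitotic genes with KO#1. The mitotic list was then lower with both guides (camera adjusted p = 0.0161 and 6.68e-05, and 0.705 and 0.546 with an estimated correlation). Of the DNA replication genes, PCNA had 1.06 and 0.44, E2F8 −1.27 and −1.74, GINS3 0.72 and 0.68, and CHAF1A −0.74 and −0.44. The replication medians were 0.18 and 0.13 (adjusted p = 0.602 and 0.417; adjusted p = 0.879 and 0.911 with an estimated correlation). That list passed without sgControl replicate 2 with KO#1 (0.0120) and KO#2 (0.00402), and with KO#2 without KO#2 replicate 3 (0.00752).

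Targets of STAT3, the transcription factor downstream of LIFR and related receptors, were lower as a list with KO#1. The median of 23 members was −0.54 with KO#1 and −0.27 with KO#2 (camera, Benjamini-Hochberg adjusted p = 0.00455 and 0.0592; adjusted p = 0.252 and 0.534 with an estimated correlation). LIFR was the 1 member that fell over all genes with each guide (limma, values above). Adjusted over the list alone, 3 passed as lower with KO#1 (LIFR, CEBPD and OSMR) and 2 with KO#2 (LIFR and OSMR). OSMR, the oncostatin M receptor, had −1.62 and −1.95, the transcription factor CEBPD −2.21 and −1.35, and PROS1 −1.65 and −1.99. With the median of neighbouring genes removed OSMR had −0.90 and −0.71, CEBPD −2.75 and −1.60, and PROS1 −1.77 and −1.64. Leaving out KO#2 replicate 1 gave 7 lower with KO#1 and 5 with KO#2, with OSMR (limma adjusted p = 0.000806 and 0.006) and CEBPD (0.00668 and 0.0398) passing in both and PROS1 (0.00429) in KO#1. OSMR in KO#2 passed without KO#2 replicate 3 (0.0455), and CEBPD in KO#1 without sgControl replicate 2 (0.0308) or KO#2 replicate 2 (0.0493). The KO#1 call held without any 1 library. The list passed with KO#2 without sgControl replicate 2 (0.0170), sgControl replicate 3 (0.0385), KO#1 replicate 1 (0.0470), KO#1 replicate 2 (0.0415) or KO#2 replicate 1 (0.003), and after GC correction (0.000795).

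Inflammatory genes were examined as NF-kB targets and as the interferon response. Of 26 NF-kB targets 1 fell with each guide: CCL2, a chemokine that attracts monocytes, fell from 339 ± 46.3 to 7.52 ± 4.56 and 6.37 ± 8.15 (log2 fold change −5.44 and −6.32, SE 0.874, limma, Benjamini-Hochberg adjusted p = 0.00915 and 0.00481). CCL28 had −1.48 and −2.10, SAA1 3.18 and 1.85, and TNFAIP2 −0.74 and −0.91. Without KO#2 replicate 1, 1 rose and 3 fell with KO#1 and 3 fell with KO#2: CCL28 (0.00218 and 0.00769) and TNFAIP2 (0.0302 and 0.0176) fell with both, and SAA1 rose with KO#1 (0.0168). When adjusted over the list alone, 1 higher (SAA1) and 1 lower (CCL2) passed with KO#1, and 2 lower (CCL2 and CCL28) with KO#2. The medians were 0.37 and 0.11 (camera adjusted p = 0.239 and 0.908; adjusted p = 0.795 and 0.951 with an estimated correlation), and with KO#2 the mean was −0.07 and the test pointed down. CCL2 in KO#1 was lost without sgControl replicate 1 or 3 or KO#1 replicate 2 or 3 (0.05001 to 0.0606), and the list passed with KO#1 without KO#1 replicate 2 (0.00509). Of 27 interferon response genes 0 passed with either guide, over all genes or adjusted over the list alone. IFITM2 had −1.52 and −0.85, IRF9 −1.29 and −0.85, and IFIT2 −1.38 and −2.19. With KO#2 replicate 1 left out 3 interferon genes, IFITM2 (0.0169) among them, fell with KO#1 and 0 with KO#2. The interferon medians were −0.00 and −0.62 (adjusted p = 0.764 and 0.189; adjusted p = 0.795 and 0.534 with an estimated correlation).

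Mesenchymal, matrix and invasion genes bear on the invasion named in the series title. Of 41 members, 3 rose and 1 fell with KO#1, and 1 rose and 3 fell with KO#2. SNAI2, a repressor of CDH1, was listed at 0 in sgControl and had 219, 56.1 and 202 in KO#1 and 40.8, 3 and 71.1 in KO#2 (limma, Benjamini-Hochberg adjusted p = 0.00441 and 0.0462). THBS1, or thrombospondin-1, had 35323 ± 2672 in sgControl and 16609 ± 4501 in KO#1 (−1.13, adjusted p = 0.134) and fell to 5162 ± 1277 in KO#2 (−2.80, SE 0.321, adjusted p = 0.00175). COL4A1, a basement membrane collagen, had −1.15 with KO#1 (adjusted p = 0.187) and fell by 2.39 with KO#2 (SE 0.361, adjusted p = 0.00722). Chosen after their values were seen, SPARC rose (1.63, adjusted p = 0.0156) and S100A4 fell (−2.32, adjusted p = 0.0332) with KO#1, and FN1, or fibronectin, fell with KO#2 (−1.63, adjusted p = 0.0279).

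Adjusted over the list alone, 7 mesenchymal genes were higher and 6 lower with KO#1, and 4 higher and 9 lower with KO#2. The medians were 0.21 and −0.19 (camera, Benjamini-Hochberg adjusted p = 0.217 and 0.189; adjusted p = 0.684 and 0.764 with an estimated correlation). SPARC in KO#1 was lost without sgControl replicate 1 or 3 or any KO#1 library (limma adjusted p 0.0741 to 0.106), S100A4 without any sgControl or KO#1 library (0.0694 to 0.214), and SNAI2 and FN1 in KO#2 without any sgControl or KO#1 library or KO#2 replicate 3 (0.0654 to 0.168 and 0.0514 to 0.156). SNAI2 was also not called in KO#2 with 8 added before the logarithm or with the median of neighbouring genes removed (SE 1.117, 0.0858). When KO#2 replicate 1 was left out, 10 rose and 6 fell with KO#1 and 3 rose and 6 fell with KO#2, with THBS1 (0.0127) and COL4A1 (0.0168) falling with KO#1.

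Of 23 renal and epithelial identity genes, 2 rose and 2 fell with KO#1, and 1 rose and 2 fell with KO#2. CDH1 and DPP4 fell with both guides, as given above. EPCAM, an epithelial adhesion molecule, rose from 4.93 ± 0.0641 to 57.1 ± 13.0 and 257 ± 142 (log2 fold change 3.27 and 5.23, SE 0.535, limma, Benjamini-Hochberg adjusted p = 0.00999 and 0.000764). ESRP1, a splicing factor of epithelia, had 3.12 and 3.88 (adjusted p = 0.132 and 0.0563), and passed without KO#2 replicate 1 (0.021 and 0.00893) and, in KO#2, without sgControl replicate 1 (0.035). With KO#2 replicate 1 left out, 3 rose and 4 fell with KO#1, and 5 rose and 6 fell with KO#2. KL, or klotho, chosen after its values were seen, was listed at 0 in sgControl and had 30.8, 24.4 and 34.0 in KO#1 (adjusted p = 0.049) and 0, 24.0 and 25.4 in KO#2 (adjusted p = 0.244). With p adjusted over the list alone, 3 were higher and 3 lower with KO#1, and 3 higher and 2 lower with KO#2. The medians were −0.48 and −0.34 (camera adjusted p = 0.268 and 0.785; adjusted p = 0.684 and 0.911 with an estimated correlation), and with KO#2 the mean was 0.07. In KO#1, EPCAM was lost without sgControl replicate 1 or 3 or KO#1 replicate 2 or 3 (0.0544 to 0.0676), and KL without any sgControl or KO#1 library or KO#2 replicate 3 (0.0501 to 0.207).

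Among 33 hypoxia-inducible factor targets, 3 rose with KO#1 and 0 were called with KO#2. CA12, a carbonic anhydrase, rose from 29.7 ± 1.80 to 141 ± 47.2 with KO#1 (log2 fold change 2.15, SE 0.444, limma, Benjamini-Hochberg adjusted p = 0.0321), and PKM, a pyruvate kinase, by 1.31 (SE 0.292, adjusted p = 0.0475). STC2, also on this list, was the third. With KO#2, CA12 had 1.95 and PKM 0.90, and SLC2A3, a glucose transporter, had 1.53 and 2.00. Leaving out KO#2 replicate 1 gave 6 higher and 1 lower with KO#1 and 4 higher with KO#2, with CA12 passing in KO#2 (0.0246) and SLC2A3 in both (0.0394 and 0.0354). In KO#2 both also passed without KO#2 replicate 2 (0.0227 and 0.0424). Adjusted over the list alone, 3 were higher with KO#1 (CA12, STC2 and PKM) and 2 with KO#2 (CA12 and SLC2A3). The medians were 0.16 and 0.21 (camera adjusted p = 0.143 and 0.189; adjusted p = 0.684 and 0.534 with an estimated correlation). In KO#1, CA12 was lost without any sgControl or KO#1 library (0.0741 to 0.191), PKM without these or KO#2 replicate 3 (0.0603 to 0.237), and STC2 likewise (0.0531 to 0.261). With the median of neighbouring genes removed CA12 had 1.70 (SE 0.492, 0.1125) and PKM 0.73 (SE 0.423, 0.570).

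Of 29 NRF2 target and ferroptosis genes, 1 fell with each guide, over all genes and adjusted over the list alone. CBR1, a carbonyl reductase, had signals of 71.9, 108 and 106 in sgControl and of 1.44, 1.44 and 0 in KO#1, and was listed at 0 in KO#2 (limma, Benjamini-Hochberg adjusted p = 0.00126 and 0.000685). KEAP1, the repressor of NRF2, had −0.86 and −0.46, and NFE2L2, which encodes NRF2, −1.02 and −1.66. In all, 4 of these fell with KO#1, KEAP1 (0.0153) and NFE2L2 (0.00819) among them, and 1 rose and 2 fell with KO#2, without KO#2 replicate 1. The medians were 0.09 and −0.16 (camera adjusted p = 0.602 and 0.417; adjusted p = 0.795 and 0.911 with an estimated correlation), and with KO#1 the mean was −0.18 and the test pointed down. Of 24 FOXO targets 0 passed with either guide with all libraries. INSR, the insulin receptor, had −2.44 and −1.26, PLXNA2 2.99 and 3.07, BCL6 −1.05 and −1.60, and CAT, or catalase, −0.93 and −1.27. With KO#2 replicate 1 left out, 3 rose and 5 fell with KO#1, including INSR (0.0175), PLXNA2 (0.0145) and CAT (0.0246), and 0 with KO#2. When adjusted over the list alone, 1 higher and 2 lower passed with KO#1 and 0 with KO#2. The FOXO medians were −0.36 and −0.35 (adjusted p = 0.143 and 0.189; adjusted p = 0.684 and 0.870 with an estimated correlation), and the list passed without sgControl replicate 2 with KO#1 (0.0185) and KO#2 (0.0195).

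The remaining lists track RNA handling and other cell types. Of 18 replication-dependent histones, whose transcripts lack poly(A) tails, 0 passed over all genes or adjusted over the list alone. As a list they were higher with KO#2 (median log2 fold change 1.69, camera, Benjamini-Hochberg adjusted p = 2.31e-06; adjusted p = 0.724 with an estimated correlation) and not called with KO#1 (−0.35, adjusted p = 0.281; adjusted p = 0.795 with an estimated correlation). HIST2H2BE had signals of 7570, 6704 and 985 in KO#2 and of 463 to 1833 in the other libraries, HIST1H2BJ 2706, 2312 and 192 in KO#2, and HIST1H2BK 3387, 2570 and 599, which passed in KO#2 without KO#2 replicate 3 (limma adjusted p = 0.0267). HIST2H4A had 231, 58.3 and 9.89. The KO#2 call held without any 1 library, and the list passed with KO#1 without sgControl replicate 3 (0.0173) or KO#1 replicate 2 (0.00422).

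Of 13 mitochondrially encoded messenger RNAs 0 passed with either guide, over all genes or adjusted over the list alone. MT-ND2 had −0.86 and −0.17, MT-ND1 −0.83 and −0.09, MT-CO2 0.27 and 0.37, and MT-ATP6 0.14 and 0.27. When KO#2 replicate 1 was left out MT-ND2 fell with KO#1 (limma adjusted p = 0.0394). The medians were −0.01 and 0.12 (camera, Benjamini-Hochberg adjusted p = 0.281 and 0.417; adjusted p = 0.795 and 0.911 with an estimated correlation). Of 45 cytosolic ribosomal protein genes 0 passed likewise; RPLP1 had 0.85 and 1.07, RPS20 0.79 and 0.77, RPL13 0.42 and 0.58, and RPS7 −0.33 and −1.1. Leaving out KO#2 replicate 1 gave 3 higher and 1 lower ribosomal genes with KO#1 and 3 higher with KO#2, RPLP1 (0.0282 and 0.0151) and RPS20 (0.0335 and 0.0185) rising with both. With all libraries and the median of neighbouring genes removed, RPLP1 had 0.26 and 0.59, and RPS20 0.25 and 0.64. The ribosomal medians were 0.10 and 0.08 (adjusted p = 0.315 and 0.417; adjusted p = 0.795 and 0.911 with an estimated correlation). That list passed with KO#1 without KO#1 replicate 2 (0.0256) and with KO#2 without KO#2 replicate 1 (0.003). Of 24 immediate early and heat shock genes 0 passed over all genes; adjusted over the list alone, 0 passed with KO#1 and 1, KLF2, as higher with KO#2. KLF2 had 0.84 and 2.31, KLF4 1.45 and 1.63, EGR1 −2.69 and −1.59, and ATF3 0.64 and 0.80. EGR1 fell with both guides (0.0129 and 0.0219) and KLF2 rose with KO#2 (0.0154) without KO#2 replicate 1, and KLF2 passed in KO#2 without KO#2 replicate 2 (0.0449). Their medians were 0.49 and 0.03 (adjusted p = 0.239 and 0.785; adjusted p = 0.684 and 0.911 with an estimated correlation). Of 38 markers of immune, endothelial, fibroblast, blood and liver cells only 4 were abundant enough to test, too few for a list test, and 0 were called, over all genes or adjusted over the list alone. ITGAM had 1.49 and 1.93, PDGFRB −0.85 and −0.75, ACTA2 0.45 and 0.83, and COL1A1 1.08 and −0.08.

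Neighbouring genes moved together along some chromosomes with both guides. In 215 windows of 51 to 99 tested genes in chromosomal order, the last of a chromosome being the longer ones, with called genes left out, the median log2 fold change passed 0.3 in the same direction with both guides in 26 windows, where 100 shuffled gene orders gave at most 0. After GC correction there were 37 (20 higher, 17 lower). All 6 windows of chromosome 20 were higher (chromosome medians 0.59 and 0.51 with KO#1 and KO#2), as were 4 of 7 on chromosome 15 and 5 of 7 on chromosome 8. Lower windows lay on chromosomes 2 (6 of 15), 19 (6 of 14), 7 (3 of 10) and 5 (2 of 9). With GC correction, of the genes named by the rule LIFR, DAB2, SEMA5A, LPCAT1, HMGCS1, OSMR, CCL28 and ELOVL7 lay in lower windows of chromosome 5, RHOB, LPIN1, CENPA and RPS7 in those of chromosome 2, and INSR, CHAF1A and KEAP1 in those of chromosome 19. In higher windows lay CDH13, ZNF469, SLC7A5, GINS3 and RPL13 (chromosome 16), SNAI2, TNFRSF10A, TNFRSF10B, DECR1, FDFT1, ESRP1 and RPS20 (chromosome 8), CA12, PKM, AEN, ETFA and RPLP1 (chromosome 15), FITM2 and PCNA (chromosome 20) and FASN (chromosome 17). Other genes had changes opposite to their window: CDH1 and CEBPD in higher windows of chromosomes 16 and 8, IL31RA in a lower window of chromosome 5, EPCAM and DYSF in those of chromosome 2, and ANGPTL4 and KLF2 in those of chromosome 19. The windows and their limit of 0.3 were chosen after seeing the data. So was removal of the neighbours' median. It left ETFA at 0.44 and −0.03 with KO#1 and KO#2, DECR1 at 0.72 and 0.28, and FITM2 at 0.68 and 0.70. KEAP1 then had −0.21 and −0.22, and INSR −1.97 and −1.16.

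**Figure D4:**
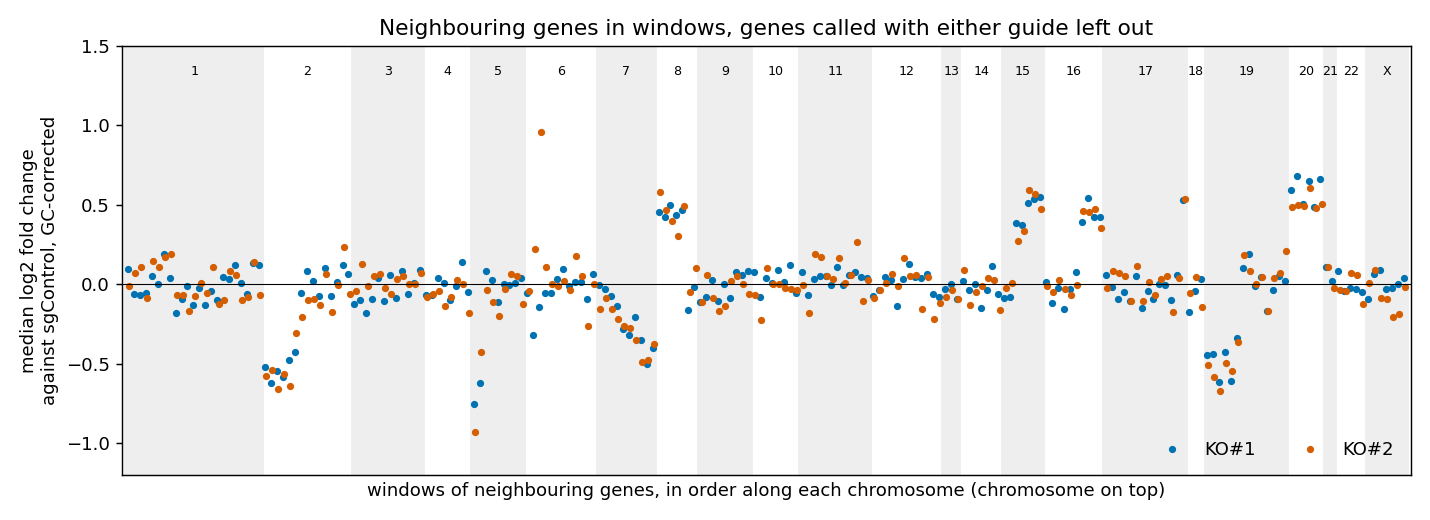
GC-corrected median log2 fold change with KO#1 and KO#2 in 215 windows of 51 to 99 neighbouring genes, arranged by chromosome; genes called by the test are left out. The 6 windows of chromosome 20 lay above 0 with both guides (chromosome medians 0.59 and 0.51).

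The guides were then compared with each other. No gene differed between KO#2 and KO#1: 0 of 12985 passed limma's test, with 529 at an unadjusted p under 0.05 where 649.25 were expected by chance. Other settings gave 0 to 30 genes, and leaving out KO#2 replicate 1 gave 13 (7 higher and 6 lower in KO#2). SLC17A1, a sodium phosphate transporter of the kidney, and CLCN7, a lysosomal chloride transporter, were among these 13 and were chosen after their values were seen. SLC17A1 had 206, 147 and 209 in sgControl, 13.0, 26.9 and 24.6 in KO#1 and 178, 252 and 247 in KO#2 (Benjamini-Hochberg adjusted p = 0.0563 with all libraries, 0.0125 without KO#2 replicate 1). CLCN7 had 0.889, 0 and 0 in sgControl, 1.44, 5.44 and 0 in KO#1 and 522, 122 and 157 in KO#2 (adjusted p = 0.072 and 0.0301). THBS1 differed by −1.68 (adjusted p = 0.325).

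**Figure D5:**
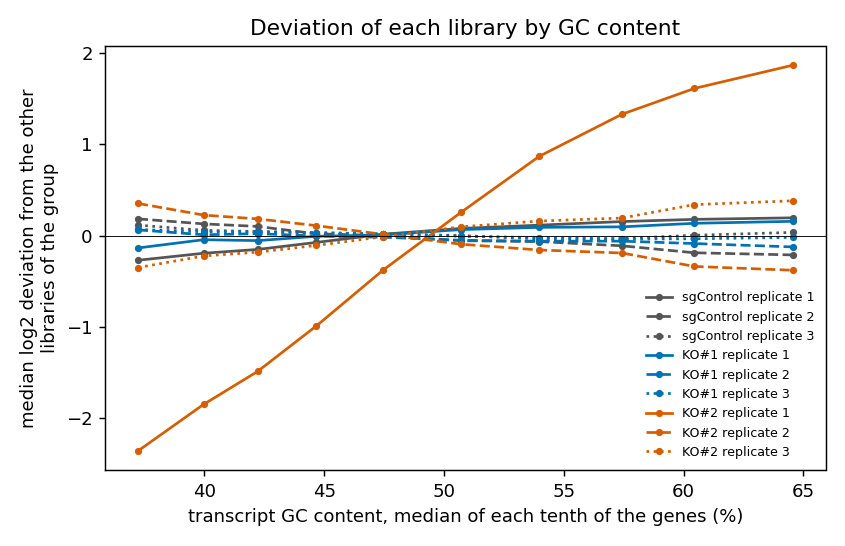
Median log2 deviation of each library from the other libraries of its group, by bin of transcript GC content; KO#2 replicate 1 was left out of the libraries compared with, so KO#2 replicates 2 and 3 are set against each other. KO#2 replicate 1 ran from −2.36 at a GC content of 37.2% to 1.87 at 64.6%, while all other libraries stayed within −0.381 and 0.381.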

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

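Except for the comparison of the genes called alike with their chromosomal neighbours and the settings named in the methods as written before the data were examined, the tests in this part were chosen after the result was seen.

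Gene lists drew attention because the effects of the 2 guides differed in a test of the difference itself (KO#2 minus KO#1, median log2 difference, camera, Benjamini-Hochberg adjusted p). The replication-dependent histones differed by 2.108 (adjusted p = 3.99e-14; adjusted p = 0.488 with an estimated correlation) and the mesenchymal, matrix and invasion genes by −0.5781 (adjusted p = 8.5e-07; adjusted p = 0.261 with an estimated correlation), and both calls held without any 1 library. Fatty acid synthesis and SREBP1 targets differed by 0.4747 (adjusted p = 0.00328; adjusted p = 0.488 with an estimated correlation), not passing without KO#1 replicate 1 (0.0511) or KO#2 replicate 2 (0.148). Cholesterol synthesis and SREBP2 targets differed by 0.4773 (adjusted p = 0.000435; adjusted p = 0.489 with an estimated correlation), not passing without KO#1 replicate 1 (0.0514) or KO#2 replicate 2 (0.189). ATF4 targets differed by 0.3747 (adjusted p = 0.00239; adjusted p = 0.489 with an estimated correlation), not passing without KO#1 replicate 2 (0.0571) or KO#2 replicate 3 (0.0888). NF-kB targets and inflammatory mediators differed by −0.3943 (adjusted p = 0.0448; adjusted p = 0.719 with an estimated correlation), not passing without KO#1 replicate 1 (0.747), KO#1 replicate 3 (0.121), KO#2 replicate 2 (0.545) or KO#2 replicate 3 (0.110). Mitochondrially encoded messenger RNAs differed by 0.1285 (adjusted p = 0.0148; adjusted p = 0.489 with an estimated correlation), not passing without KO#2 replicate 1 (0.0996) or KO#2 replicate 3 (0.0888). Other lists passed in other fits. After GC correction these were elongation (0.00308), the interferon response (0.0279) and immediate early genes (0.0315), and without KO#2 replicate 1 they were elongation (4.97e-05), the unfolded protein response (0.00177), the interferon response (0.028), ribosomal proteins (0.000905) and immediate early genes (0.0164). Elongation (0.0462) and p53 targets (0.037) passed without KO#1 replicate 2, and DNA replication without KO#1 replicate 2 (0.00862) or KO#2 replicate 3 (0.00761). Mitotic genes passed without KO#1 replicate 1 (0.000104), KO#1 replicate 2 (0.00136) or KO#2 replicate 2 (0.00287). All 7 differences passed after GC correction, and 0 of 7 with an estimated correlation or with fry.

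KO#2 replicate 1 stood apart from the other libraries. Few reads alone are argued against: its deviations from the other KO#2 libraries had an SD of 1.336 in 89 genes of mean 8000 or more and 1.831 in genes of 100 to 200, a ratio of 0.7296, where sampling of reads would leave abundant genes nearly unmoved. An sgControl library under the wrong label is argued against too. After GC correction 80.1% of 397 genes, chosen for a large change with KO#1 without this library, were nearer to the KO#1 mean than to sgControl. In KO#2 replicates 2 and 3, which entered neither mean, the shares were 81.11% and 88.92%. The sgControl libraries had 0.252% to 1.76%, but they entered the sgControl mean and the choice of genes, so low shares were built in. Without the correction, where that test was first run, the share in KO#2 replicate 1 was 64.54%, between the bounds set for it. A bias with GC content is consistent with the deviations, which correlated with transcript GC content at r = 0.8248 across genes (−0.3002 to 0.3429 in the other libraries). A KO#1 library under the KO#2 label cannot be told apart and stays open: it lay nearer to the other KO#2 libraries than to KO#1 in 30.77% of 13 genes that differed between the guides without it, and in 69.23% of 13 found after GC correction. Both shares lie between the bounds, values go both ways, and no biological explanation was tested.

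Genes changed alike with both guides were weighed next. Gain or loss of chromosomal blocks is argued against as the whole cause: the median change of their neighbours in the gene's own direction was 0.11, where the genes themselves had a median change of 3.867, although for 20 of 172 the neighbours' median was at least 0.58. Added cells of another kind in the KO libraries are argued against as well, since 13 genes called lower had means under 5% of sgControl with both guides, which added cells cannot bring about by dilution unless they replace nearly all others. A change particular to the sgControl population cannot be told apart from an effect of ELOVL5 targeting: both guides correlated at r = 0.73139, but there was a single sgControl population. Whether the changes come from loss of ELOVL5 or from the history of the cell populations therefore stays open.

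Neighbouring genes shifted together with both guides. Chance order of genes is argued against, as 26 windows were shifted alike and shuffled orders gave at most 0, and so is the GC content of the regions, as 37 windows were shifted after correction. A different number of chromosome copies in the sgControl and KO populations is consistent with the finding that 81.47% of 2062 genes in windows shifted with KO#1 against sgControl replicate 1 moved the same way with KO#2 against the other 2 sgControl libraries (62.79% without GC correction). No DNA data were used here, so copy number itself was not measured.

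Random regroupings of the libraries were counted for each number of called genes. For KO#1 (303 genes, highest other 0), KO#2 (265, highest other 0) and KO#2 against KO#1 (0, highest other 0), with as many genes in 1, 1 and 10 of 10 splits, the 10 splits are too few for a share under 0.05. For the mean of both guides 1 of 100 splits gave 403 genes or more (highest other 24), and for the genes called alike 1 of 100 gave 179 or more (highest other 0). In both cases that 1 was the actual grouping, so 1 of 100 is the smallest share possible. Chance in the grouping of these 9 libraries is therefore argued against for these 2 counts but not excluded. The splits took no account of any pairing by place in sample order. Chance between cultures was not tested, as the labels do not say that replicates are separate cultures.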

How the results depend on the processing

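The GC content correction, the same genes without it, removal of the neighbours' median and the replicate block, alone and with GC correction, were chosen after seeing the data, and the other settings before. Of the results for single named genes under the alternatives 7476 kept their side of the threshold, 560 came to pass and 281 no longer passed. Among results that passed in either fit 0 changed sign. Sign changes of results that passed in neither fit were not counted. FASN with KO#1, for example, went from 0.33 to −0.22 with the median of neighbouring genes removed. Lists did change direction without KO#2 replicate 1. The median difference of the unfolded protein response went from −0.16 to 0.29 (camera adjusted p 0.775 and 0.00177). Without passing, camera's direction also turned for the differences of mitotic genes, FOXO and hypoxia targets and, with KO#2, for mitochondrial messenger RNAs and immediate early genes. Medians alone turned for fatty acid synthesis, oxidation, apoptosis and NRF2 targets with KO#2 and for the differences of lipid droplets, replication, apoptosis, renal identity and ribosomal proteins, the last passing there (0.000905). For genes called with KO#1, KO#2, the mean of both and alike (303, 265, 403 and 179), a mean of at least 100 gave 105, 103, 152 and 62, where fewer genes were tested. arrayWeights gave 2765, 1293, 2808 and 1125, and GC correction 1053, 972, 1424 and 629. With only the 2 groups compared there were 1883 for KO#1 and 79 for KO#2. Genes differing between the guides numbered 0 with limma (529 at an unadjusted p under 0.05), 4 with pseudocount 8, 2 with quantile normalization again, 2 with no trend, 24 with arrayWeights and 11 with GC correction. ELOVL5 passed with arrayWeights (log2 fold change −1.043 with KO#1, −1.038 with KO#2), with GC correction (−1.203 and −0.9328) and with only the 2 groups compared (KO#1, −1.115). Gene lists called numbered 4 for KO#1, 3 for KO#2 and 7 for the difference, and 0, 0 and 0 both with camera with the correlation estimated per list and with fry. Leaving out each library in turn gave 96 (without KO#1 replicate 1) to 1592 genes for KO#1, 95 (without sgControl replicate 1) to 1042 for KO#2, 155 (without sgControl replicate 1) to 1897 for the mean, 66 (without sgControl replicate 1) to 798 alike and 0 to 13 between the guides, each highest count without KO#2 replicate 1. For the mean of both guides it also gave 156 without sgControl replicate 3, 219 without sgControl replicate 2, and 253, 250 and 224 without KO#1 replicates 1, 2 and 3. Lists ranged from 2 (without KO#1 replicate 3 or KO#2 replicate 3) to 10 (without KO#1 replicate 2; 8 without sgControl replicate 3) for KO#1, from 3 to 6 for KO#2 (6 without sgControl replicate 2 or KO#2 replicate 1; 5 without sgControl replicate 3, KO#1 replicate 1 or KO#1 replicate 2), and from 5 to 11 for the difference (11 without KO#2 replicate 1). The ELOVL5 log2 fold change ranged from −1.306 to −0.9356 with KO#1 and from −1.829 to −0.8028 with KO#2. The causes of these changes between settings were not tested. With a mean of at least 100 fewer genes were tested, but 12 results for named genes that were still tested no longer passed. Replicate numbers follow sample order, and the labels do not say whether libraries with the same place were paired. As a hint from the data alone, deviations from group means correlated at 0.191 to 0.543 for the 9 pairs of libraries with the same place and at −0.448 to 0.157 for others, each library correlating best with its own place. The replicate block gave 340, 313, 536 and 197 genes and 0 between the guides (840 at an unadjusted p under 0.05), lists of 6, 4 and 7, and ELOVL5 at 0.161 and 0.0917 (limma adjusted p). Among the calls it changed, MKI67, ASPM and CENPF passed with KO#2, the mitotic list with KO#1 (camera 0.0161), KO#2 (6.68e-05) and the difference (0.0239) and cholesterol synthesis with KO#1 (0.0277), and the NF-kB difference did not (0.0774). With GC correction added it gave 1677, 1819, 2225 and 1071 genes, 30 between the guides, lists of 7, 5 and 10, and ELOVL5 passing (−1.203 and −0.9328). Alternatives for raw counts were not run because the table holds normalized values. Low values in KO#2 replicate 1 rest on few reads: 10 reads had a value of 55.667 there.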

Other observations

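The genes and values in this part were chosen after their values were seen, and no test here was planned.

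Among other genes called with both guides, TGM2, a transglutaminase that crosslinks matrix proteins, rose from 824 ± 263 to 9435 ± 1503 and 8164 ± 4440 (SD, n = 3; log2 fold change 3.56 and 3.15, limma, Benjamini-Hochberg adjusted p = 0.00407 and 0.00805). PLAT, the tissue plasminogen activator, rose by 2.80 and 2.65 (adjusted p = 0.0144 and 0.0215). PLTP, a phospholipid transfer protein, rose by 1.97 and 2.21 (adjusted p = 0.0332 and 0.0219), and SCARB1, a receptor for high-density lipoprotein, by 1.93 and 2.11 (adjusted p = 0.0267 and 0.0186). SLC7A2, a transporter of cationic amino acids, rose from 12.9 ± 3.64 to 277 ± 49.0 and 352 ± 214 (4.34 and 4.46, adjusted p = 0.00203 and 0.0018). ENG, or endoglin, a coreceptor for TGF-beta, rose by 4.49 and 3.50 (adjusted p = 0.00409 and 0.016). The neighbours of SLC7A2, TGM2, PLAT and PLTP were shifted the same way, with medians of 0.827, 0.712, 0.590 and 0.402 on the log2 scale.

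FGFR2, a fibroblast growth factor receptor, fell from 2572 ± 853 to 295 ± 104 and 542 ± 257 (log2 fold change −3.12 and −2.28, limma, Benjamini-Hochberg adjusted p = 0.00441 and 0.0246). PAPPA, a protease that cleaves insulin-like growth factor binding proteins, fell with both guides (−3.50 and −5.24; adjusted p = 0.0262 and 0.00372). SALL1, a transcription factor of kidney development, had signals of 117, 96.0 and 90.8 in sgControl and was listed at 0 in all 6 KO libraries. FBXL7, an F-box protein gene, had 341, 310 and 270 in sgControl, 0, 0.444 and 0 in KO#1 and 0, 1 and 0.778 in KO#2. In the gene's own direction the neighbours' median was 0.6195 for FBXL7 and −0.5265 for SALL1. With a limit of 3 or less in every library of 1 group and 100 or more in every library of the other, 3 genes (GYPC, HYDIN and MYADM) were on and 1 (FBXL7) was off with both guides, and without KO#2 replicate 1 there were 4 on, with TRPS1 added.

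The median deviation of the mitotic genes from their mean over all libraries was 1.306, 1.469 and 1.073 in replicate 2 of sgControl, KO#1 and KO#2, and −1.229 to −0.2192 in the other 6 libraries. DNA replication genes had 0.6225, 0.7022 and 0.9984 in the same 3 libraries and −0.6229 to −0.03093 in the others. The replication-dependent histones stood at 2.387 and 2.271 in KO#2 replicates 1 and 2 and at −0.8116 in KO#2 replicate 3.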
